A study of Mus musculus with 6 samples.

How the data were processed

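Bone marrow cells of C57BL/6 mice, a common inbred laboratory strain, were profiled by single-cell RNA sequencing after hindlimb ischemia, an operation that reduces the blood supply of a leg, or after a sham operation. Per the labels, sorted marrow leukocytes (lineage-positive) and sorted hematopoietic stem and progenitor cells (lineage-negative) were each collected in sham mice and on days 2 and 7 after ischemia. The day on which sham marrow was collected is not given in the sources used here. The 6 samples of the series hold 23 libraries, each marked by its own cell tag. There were 12 lineage-positive libraries, 4 per group (sham tags 301 to 304, day 2 tags 305 to 308, day 7 tags 309 to 312). The 11 lineage-negative libraries were 3 sham (tags 302 to 304), 4 of day 2 (tags 305 to 308) and 4 of day 7 (tags 309 to 312). Libraries are named here by tag.

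The labels' protocols describe RNA extraction from sorted cells with a Pico Pure kit and standard Illumina library preparation. The submitters' processing notes name Partek 10.0.22.1204 and the genome build mm10. The aligner, the counting program and the cell caller are not given in the sources used here. In the lineage-positive compartment the authors deposited whole-number counts of unique molecular identifiers (UMIs) per gene and cell, for 32285 genes. These matrices also held counts of the 12 cell tags, which made up 24.9% to 39.2% of all counts in a library and were kept out of library sizes and tests. In the lineage-negative compartment the authors deposited expected counts, meaning values per gene and cell that need not be whole, for 15939 genes. The expected counts were summed per library and class and then rounded to whole numbers before any count test. The design had assumed whole counts in both compartments.

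Cells with at least 200 detected genes and under 15% of counts from mitochondrial genes were kept, which left 16268 of 16885 lineage-positive and 9348 of 9836 lineage-negative cells. Each compartment was clustered on its own with scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9), using 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5 and seed 1. A cluster was named from 17 fixed marker lists where at least 3 markers of a class stood among its 50 genes with the highest fold over the mean of the other clusters. Folds were computed on counts scaled to 10000 per cell, with an offset of 0.1, over genes with a mean above 0.5. A cluster stayed unnamed where another class had as many of these markers or had more among the top 10 genes, and clusters of one name were summed into a class. No doublets were removed. The automatic threshold of Scrublet, run through scanpy, marked 0 cells in both compartments and was judged not to have worked. The 95th percentile of its score was 0.178 in lineage-positive and 0.187 in lineage-negative cells.

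Counts were summed per library over all kept cells and over each of the 3 largest eligible classes of a compartment, and the library was the replicate. A library with under 20 cells of a class stayed out of that fit, which removed library 307 (6 cells) from the stem-like class. Sums were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) after filterByExpr and TMM scaling, by quasi-likelihood tests with the 3 groups in one fit and no covariate. The contrasts were day 2 minus sham, day 7 minus sham and day 7 minus day 2, with Benjamini-Hochberg adjustment over genes at a threshold of 0.05. All adjusted p-values of single genes given here are from this edgeR test unless DESeq2 1.42.0 is named. Because both ischemia contrasts use the same sham libraries, no overlap or correlation of them was computed, and the days were compared by their own contrast. The 28 gene lists and the 17 marker lists were tested with camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data. Over the 28 gene lists, 206 of 669 tests passed with the preset value and 3 passed with the estimated one. Class shares were compared by exact permutation of libraries, with the smaller tail doubled for a two-sided p, for classes with a mean share of at least 0.5%. Array and statistics libraries were numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

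The groups, tests, contrasts, markers, gene lists and the rule for named genes were fixed before the data were examined. The rule took, among genes with an adjusted p under 0.05, up to 10 rises and 10 falls per contrast with sham, or 5 and 5 for day 7 against day 2. Those genes needed a mean of at least 20 CPM, the count scaled to library size, in the higher group and no overlap of library values between groups. It added up to 4 members of each passing list and up to 2 significant members of any list. Predicted genes, immunoglobulin and T cell receptor segments, hemoglobin genes, Xist and Y-linked genes were only counted. The rule gave 710 entries of a gene in a contrast, of which 148 are named in the text. These 148, all with an adjusted p under 0.05, were picked from the 710 after their values had been seen, so as to cover each gene group. Results for 4 other genes are not reported here. Gene positions are from GENCODE vM21 on GRCm38, whose build may not be the one the authors used.

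The pipeline was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed between day 2 and sham. At a 2-fold change, 76.1% of changed genes were recovered in neutrophil-like cells, 52.2% in lineage-positive monocyte-like cells and 28.4% in lineage-positive erythroid-like cells. In lineage-negative cells the recovery at this fold was 77.6% for the stem-like, 83.6% for the monocyte-like and 80.6% for the erythroid-like class. At a 3-fold change it was 98.5% in neutrophil-like, 78.8% in lineage-positive monocyte-like and 75.8% in lineage-positive erythroid-like cells. Of all calls, 5.42% were false in the neutrophil-like class and 7.55% in the lineage-positive monocyte-like class.

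Alternatives were RLE scaling, no low-count filter, DESeq2, all deposited cells, Leiden resolution 1.0, each library left out, the library number as a block in lineage-positive fits, and removal of lineage-negative libraries with under 200 kept cells. Alternatives chosen after seeing the data were the removal of the 5% of cells with the highest Scrublet scores, the removal of clusters with a median score over 0.15, and separate fits of neutrophil clusters 1 and 2. Added in the same way were fits of neutrophil-like cells of 3000 to 8000 UMIs, drawn to the same number per library in each bin of 250 UMIs, over the class (324 cells per library) or within each of clusters 0, 1 and 2 (211 cells per library), and of 324 cells per library drawn at random. Also added were Leiden resolution 1.0 with 3 unnamed clusters joined to the neutrophil-like class, since neutrophil markers were the most frequent in them, and lineage-positive fits without sham libraries 301 and 302 or without 303 and 304. The labels do not say that libraries are separate animals, so p-values measure the spread between these libraries, which may be technical. No pair of libraries in a group agreed within sampling noise. Over all kept cells the chi-square per degree of freedom was 9.42 for lineage-positive sham libraries 301 and 302, and 6.06 for 303 and 304. Across these pairs, which also differ in cell makeup, it was 46.3 to 80.3. It was 15.9 to 52.8 on day 2 and 3.54 to 7.28 on day 7.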

Results

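Single-cell expression was measured in sorted bone marrow leukocytes and in sorted hematopoietic stem and progenitor cells of mice. The question was how both compartments differ from those of sham-operated mice 2 and 7 days after hindlimb ischemia. Lineage-positive leukocytes gave 12 libraries of 1116 to 1620 kept cells, with 6460236 to 14997307 gene counts per library. The median UMI count per cell lay between 3655 and 5310.5 in the sham libraries, between 6414 and 8180 on day 2 and between 4820.5 and 5841 on day 7. Lineage-negative cells gave 11 libraries that differed far more in size, from 96 cells and 846483 counts in day 2 library 307 to 4402 cells and 34855774 counts in day 7 library 312. Values are mean ± SD over libraries, n is the number of libraries, and fold changes are log2 values with their standard errors (SE).

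Neutrophil-like cells made up most of the lineage-positive marrow and formed 6 clusters. Cluster 1 was led by Nt5e, Mmp8 and Mmp9, cluster 2 by Il1b, Cd101 and Csf3r, cluster 0 by Ltf and Ngp, and cluster 6 by the proliferation genes Top2a and Mki67. Cluster 5 was led by the interferon-induced genes Ifit3, Ifit1 and Oasl1, and cluster 9, with Ltf and Olfm4 among its leading genes, had a median Scrublet score of 0.253. The other named lineage-positive classes were monocyte-like (Fn1, F13a1, Ccr2), granulocyte-monocyte (GM) precursor-like (Elane, Prtn3, Mpo), erythroid-like (hemoglobin genes, Alas2), B cell-like (Cd79a, Ebf1), T cell-like (Trbc2, Cd3g, with the killer cell genes Gzma and Ccl5) and basophil-like (Mcpt8, Prss34). In lineage-negative cells the named classes were stem-like (Hlf, Mecom, Adgrl4), erythroid-like (Car1, Klf1), monocyte-like (F13a1, Ms4a6c, Ly86), GM precursor-like (Elane, Prtn3), megakaryocyte-like (Pf4, Vwf), basophil-like, B cell-like and eosinophil-like. The alarmins S100a8 and S100a9 led the GM precursor-like class, the chemokine gene Cxcl2 was among the leading genes of the stem-like class, and so were Myl10 and the lymphoid progenitor gene Dntt. That class had 9 stem and 4 lymphoid progenitor markers among its top 50 genes, and at Leiden resolution 1.0 a cluster of 431 cells led by Dntt and Myl10 was named lymphoid progenitor-like. In the lineage-negative compartment 1 erythroid-like cluster with a median Scrublet score of 0.187 was led by the monocyte gene F13a1.

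On day 2 after ischemia, 706 of 10056 genes changed against sham in lineage-positive neutrophil-like cells, 341 upward and 365 downward. The rises included members of the fixed lists of alarmins, NF-kB and TNF genes, granule proteins and the phagocyte oxidase. These lists passed with the preset correlation and not with an estimated correlation (adjusted p from 0.392 to 0.49). The largest rise among the named genes was that of Wfdc17, a secreted whey acidic protein family member of activated myeloid cells. It went from 39.5 ± 18.7 to 204 ± 35.8 CPM (log2 fold change 2.40, SE 0.26, adjusted p = 0.000649, n = 4 and 4). Wfdc17 (ENSMUSG00000069792) lies on chromosome 11 at 83703991 to 83706268 on the plus strand. Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825, plus strand), an interferon-inducible membrane protein, rose from 105.0 ± 35.8 to 295 ± 57.6 CPM (1.5, SE 0.209, adjusted p = 0.000893). Acod1, which makes itaconate, rose by 1.21 and the protease Asprv1 by 1.07. The stefin A genes Stfa2, Stfa1 and Cstdc5 rose by 1.46, 0.82 and 0.82. As near-identical copies they could share reads, so their separate values are uncertain. With Acod1 and Asprv1 they led a cluster at Leiden resolution 1.0 (2397 cells), and a shift toward it was not tested.

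Of the NF-kB and TNF list, 8 of 28 measured members rose in day 2 neutrophil-like cells (12 rose and 1 fell when adjusted over the list alone, list median 0.54). Among them were Cd14, the co-receptor for endotoxin (0.78, 36.5 ± 11.8 to 62.5 ± 8.25 CPM), the mitochondrial superoxide dismutase gene Sod2 (0.71), the lectin receptor gene Clec4e (0.70) and Tnf (0.55). The list test gave an adjusted p = 2.31e-06 with the preset correlation and an adjusted p = 0.49 with an estimated correlation. Both the survival gene Mcl1 (0.86, 766 ± 286 to 1393 ± 223 CPM, adjusted p = 0.0167) and the pro-apoptotic gene Bcl2l11 (0.86, adjusted p = 0.0047) rose. For these and other activation genes sham libraries 301 and 302 lay below 303 and 304. Mcl1 stood at 443 and 619 against 1068 and 935 CPM, Cd14 at 25.02 and 27.6 against 46.1 and 47.1, Acod1 at 47.8 and 112 against 233 and 202, Clec4e at 164 and 232 against 344 and 259, and Bcl2l11 at 22.3 and 26.6 against 43.3 and 39.2. Without libraries 301 and 302 the list median was 0.23, and without 303 and 304 it was 0.90. Without 301 and 302 Mcl1 (0.48) and Bcl2l11 (0.53) rose, and Cd14 (0.42), Clec4e (0.43), Sod2 (0.45) and Acod1 (0.66) did not pass. Of the S100 and alarmin list, 5 of 16 members rose (7 when adjusted over the list alone), among them Anxa1 (0.38), Lcn2 (0.27) and Wfdc21 (0.26). The adjusted p of that list was 5.68e-06, against an adjusted p = 0.392 with an estimated correlation.

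Granule and oxidase genes of the day 2 neutrophil-like cells moved by smaller steps. Secondary and tertiary granule genes rose for 4 of 22 members (9 when adjusted over the list alone), with Hp, which encodes haptoglobin, at 0.38 and the surface antigen gene Ly6g at 0.29. The list had an adjusted p = 0.00539, and an adjusted p = 0.49 with an estimated correlation. For primary granule genes the count was 2 of 14, and 2 when adjusted over the list alone, with the protease inhibitor gene Serpinb1a at 0.39 (adjusted p = 0.00135, and adjusted p = 0.49 with an estimated correlation). NADPH oxidase and oxidative burst genes rose for 6 of 18 members (7 when adjusted over the list alone), including the oxidase subunit genes Ncf4 (0.26) and Cyba (0.19), the glutathione synthesis gene Gclm (0.47) and the thioredoxin reductase gene Txnrd1 (0.40). Their list test gave an adjusted p = 0.000501, and an adjusted p = 0.392 with an estimated correlation. Mitochondrially encoded transcripts rose for 5 of 13 members (6 when adjusted over the list alone, adjusted p = 2.11e-05, and adjusted p = 0.49 with an estimated correlation), with mt-Co1 at 0.46 and mt-Co2 at 0.37. Over all kept lineage-positive cells the median mitochondrial share of counts per cell was higher in every day 2 library (0.521% to 0.734%) than in any sham library (0.323% to 0.428%), and 0.35% to 0.434% on day 7. Cells at or over the limit of 15% had been left out, 8 to 42 per library on day 2 and 1 to 6 in sham. The glycolysis genes Gapdh (0.29) and Ldha (0.25) rose as well. The mitosis list had a median of 0.26 with 0 of 33 members past the edgeR threshold and 0 when adjusted over the list alone (adjusted p = 2.31e-06, and adjusted p = 0.536 with an estimated correlation). Neutrophil markers moved with these groups, 3 of 17 rising (8 rose and 1 fell when adjusted over the list alone, adjusted p = 0.0239, and adjusted p = 0.546 with an estimated correlation). GM precursor markers in the same cells had 1 of 13 members rising (4 when adjusted over the list alone, list median 0.27, adjusted p = 0.0239, and adjusted p = 0.546 with an estimated correlation).

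Genes that fell in day 2 neutrophil-like cells included Maml3, a Notch co-activator (34.3 ± 6.16 to 15.3 ± 2.64 CPM, log2 fold change -1.15, SE 0.152, adjusted p = 0.000649). The matrix glycoprotein gene Thbs1 (-1.10), the syntrophin gene Sntb1 (-1.09) and the receptor kinase gene Grk5 (-1.0) fell. So did the NF-kB-inducing kinase gene Map3k14 (-0.95) and the salt-inducible kinase gene Sik1 (-0.86). The maturation marker Cd101 fell by 0.81. At Leiden resolution 1.0 it stood at 0.15 in a class without 3 clusters led by Cd101 (1147 cells), Il1b (1055 cells) and Ifit1 (397 cells), which had too few neutrophil markers for a name, and with these clusters joined to the class it fell by 0.76. Library values of Thbs1 overlapped between the groups. The histone gene Hist1h2ac (-1.08) belongs to a family of near-identical copies, which makes its value uncertain. Of the interferon response list 1 of 32 members fell, Ifi204 (-0.85), and 1 when adjusted over the list alone, with a list median of -0.26 (adjusted p = 0.000388, and adjusted p = 0.559 with an estimated correlation). The MHC class I list had 0 of 15 members past the edgeR threshold and a median of -0.20 (2 fell when adjusted over the list alone, adjusted p = 0.0308, and adjusted p = 0.562 with an estimated correlation). The makeup of the class moved with these genes. Cluster 2, led by Il1b, Cd101 and Csf3r, held 29.5% ± 5.67 of kept cells in sham, 18.2% ± 2.68 on day 2 and 25.03% ± 3.36 on day 7. The interferon-led cluster 5 held 2.96% ± 1.22, 1.48% ± 0.742 and 1.39% ± 0.517. These cluster shares, which the same genes help to set, were not tested. With clusters 1 and 2 fitted alone, Cd101 stood at -0.26 and -0.55 and Ifi204 at -0.30 and -0.43, none of them past the threshold. At Leiden resolution 1.0 Ifi204 stood at -0.029 in the class without the Ifit1-led cluster and fell by 0.79 with the 3 clusters joined.

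The day 2 count in neutrophil-like cells depended on single libraries: it was 236 without library 308, 282 without 305, 339 without 307, 436 without sham library 302 and 1329 without sham library 304. It was 411 without both 301 and 302 and 2169 without both 303 and 304, with 29 and 32 of the 36 genes named above passing. Libraries 301 and 302 both lay farther from day 2 than 303 and 304 for 9 of the 36 and both nearer for 10, where chance gives 16.7% each. Of the 36, 22 passed without library 308, 23 without 305, 28 without 307, 29 without 306 and 32 to 36 without any other single library. DESeq2 called 392 genes higher and 462 lower. Fitted alone, cluster 1 gave 220 changed genes and cluster 2 gave 264, with 24 and 22 of the 36 named genes passing, and 26 passed at Leiden resolution 1.0, or 36 with the 3 unnamed clusters joined. Cells of day 2 had the higher UMI counts stated above. Among 324 cells per library drawn to like UMI counts, cluster 2 took 33.3% to 35.2% on day 2 and 9.57% to 26.9% in sham. There 16 of the 36 passed and 8 turned in sign, among them Maml3 (0.42) and Cd101, which passed in the other direction (0.61). Among 211 cells per library drawn to like UMI counts within clusters 0, 1 and 2, 14 passed, and Cd101 (0.047), Lcn2 (-0.10) and Serpinb1a (-0.044) turned in sign. Among 324 cells per library drawn at random 20 passed.

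**Figure D1:**
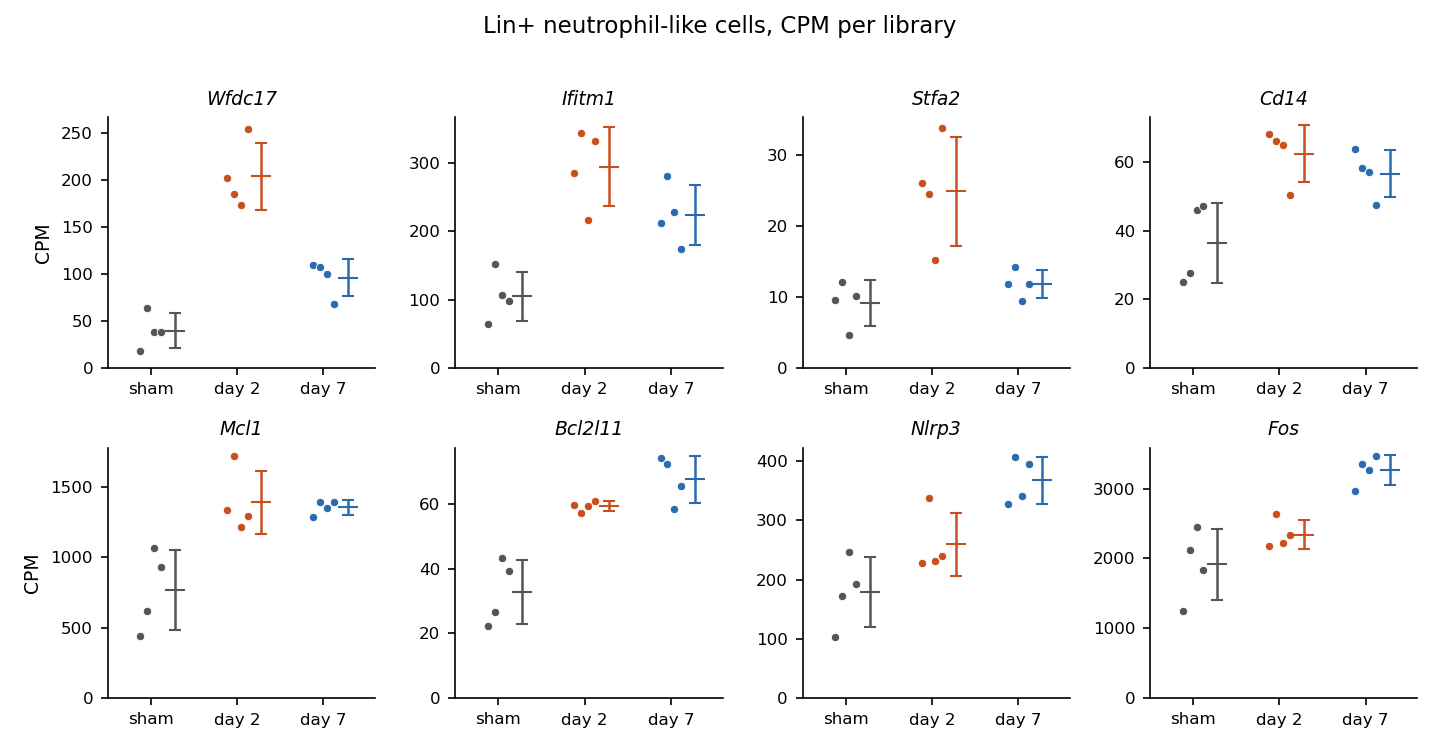
CPM of 8 genes in lineage-positive neutrophil-like cells, with 1 point per library in the sham, day 2 and day 7 groups and a bar at the mean with SD beside them. Wfdc17 lay at 39.5 ± 18.7 CPM in sham, 204 ± 35.8 on day 2 and 96.0 ± 19.2 on day 7.

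By day 7, 45 genes stood higher and 4 lower than in sham in neutrophil-like cells, of 10056 tested. Cd69, an early activation antigen, rose from 36.8 ± 8.80 to 77.4 ± 9.16 CPM (1.07, SE 0.16, adjusted p = 0.0115, n = 4 and 4). Nlrp3, the sensor of the inflammasome, rose from 178 ± 59.3 to 368 ± 39.9 CPM (1.05, adjusted p = 0.0355). The immediate early transcription factor genes Fosb (0.93), Egr1 (0.80) and Fos (0.77, 1913 ± 514 to 3262 ± 215 CPM) rose. Rises were also found for Klf4 (0.82), the stress-induced kinase gene Plk2 (0.83) and Nt5e (0.80), which encodes the ectonucleotidase CD73. Wfdc17 (1.31), Ifitm1 (1.10), Bcl2l11 (1.05), Tnf (0.67) and Anxa1 (0.35) were also above sham. The genes that fell included the phospholipase gene Pla2g4a (-0.47) and the histone genes Hist1h1e (-0.90) and Hist1h2ac (-1.16), whose reads are uncertain for the reason given above. The sham values of Hist1h1e were 829 and 794.5 CPM in libraries 301 and 302 and 409 and 439 in 303 and 304, and those of Egr1 were 208 and 255.5 against 403 and 394. Without 301 and 302, Hist1h1e (-0.36), Hist1h2ac (-0.68), Pla2g4a (-0.31) and Egr1 (0.46) did not pass.

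Among the fixed lists, NF-kB and TNF genes had a median of 0.61 in day 7 neutrophil-like cells. Over all genes 2 of 28 members rose, and 16 when adjusted over the list alone (adjusted p = 5.54e-19, and adjusted p = 0.266 with an estimated correlation). The median was 0.34 without sham libraries 301 and 302 and 0.98 without 303 and 304. For the immediate early and heat shock list the count was 3 of 25 over all genes and 13 when adjusted over the list alone (median 0.30, adjusted p = 1.81e-09, and adjusted p = 0.266 with an estimated correlation). Cell cycle inhibitor and quiescence genes rose for 2 of 16 members, Klf4 and Egr1 (8 rose and 2 fell when adjusted over the list alone, adjusted p = 0.000393, and adjusted p = 0.266 with an estimated correlation). The interferon response list had a median of -0.26 with 0 of 32 members past the edgeR threshold and 0 when adjusted over the list alone (adjusted p = 0.000111, and adjusted p = 0.505 with an estimated correlation). DESeq2 called 146 genes higher and 44 lower. The edgeR count of 49 moved with every library left out. It was 2 without 310, 7 without 311, 8 without 305, 8 without 307, 9 without 309 and 10 without 312. It was 26 without 301, 28 without 306, 29 without 308, 31 without 302, 212 without 304, 279 without 303 and 1413 without both 303 and 304. Of the 16 genes named for this contrast, 0 passed without library 310, 16 without 303 or 304, and 2 to 12 without any other single library. In cluster 1 alone 4 of the 16 passed, in cluster 2 alone 7, and among cells of like UMI counts 9, or 5 when drawn within clusters.

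Between day 2 and day 7, 15 genes rose and 71 fell in neutrophil-like cells. Thbs1 was higher on day 7 than on day 2 (402 ± 97.5 against 137 ± 48.1 CPM, 1.55, SE 0.253, adjusted p = 0.00673). Also higher were the GABA receptor gene Gabbr1 (0.75), Btbd19 (0.68), the class I gene H2-K1 (0.54) and the TGF-beta signal transducer gene Smad3 (0.53). Wfdc17 (-1.09), Cstdc5 (-1.07), Stfa2 (-1.07), Hist1h2ab (-0.71) and the ribosomal protein gene Rpl12 (-0.69) were lower. Rpl12 has many pseudogene copies, and together with the histone and stefin genes its value is uncertain. In the mitochondrially encoded list 5 of 13 members fell (8 when adjusted over the list alone, adjusted p = 5.78e-12, and adjusted p = 0.246 with an estimated correlation). The S phase list had a median of -0.33 with 0 of 28 members past the edgeR threshold over all genes. When adjusted over the list alone 12 fell (adjusted p = 2.54e-15, and adjusted p = 0.332 with an estimated correlation). DESeq2 called 48 genes higher and 126 lower. The edgeR count of 86 was 36 without library 305, 36 without 310, 44 without 312, 46 without 307, 48 without 308, 131 without 306, 136 without 302 and 141 without 301. It was 331 without both 301 and 302, 192 without both 303 and 304, 3 in cluster 1 alone and 9 in cluster 2 alone, where Rpl12 stood at 0.12. Of the 10 genes named here, 3 to 7 passed without any single day 2 or day 7 library and 5 at Leiden resolution 1.0, or 7 with the 3 unnamed clusters joined. Of the 9 of them tested in each, 0 passed in cluster 1 alone, 2 in cluster 2 alone and 2 among cells of like UMI counts.

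In lineage-positive monocyte-like cells, 118 genes rose and 121 fell on day 2, of 7573 tested. Members of the mitosis list were among the rises, and members of the MHC class II and interferon lists among the falls. Of the mitosis list, 18 of 33 members rose (33 of 33 when adjusted over the list alone, median 1.14). The kinetochore gene Cenpf rose from 32.1 ± 16.3 to 94.6 ± 12.2 CPM (1.38, SE 0.233, adjusted p = 0.0045, n = 4 and 4). Other members were the kinesin gene Kif2c (1.83), the ubiquitin-conjugating enzyme gene Ube2c (1.5), Cdca3 (1.38), Birc5 (1.28), which encodes survivin, and the cyclin gene Ccnb2 (1.17). Spdl1 (2.39), Melk (1.70), Cdkn3 (1.69), Mad2l1 (1.58) and Sgo1 (1.5), which are on none of the fixed lists, also rose. The list test gave an adjusted p = 9.72e-40, and an adjusted p = 0.135 with an estimated correlation. Several of these genes were low, and the class held between 30 and 228 cells per library.

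MHC class II genes fell on day 2 in monocyte-like cells for 3 of 6 measured members (5 when adjusted over the list alone, median -1.61). H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand) fell from 199 ± 101 to 50.4 ± 22.2 CPM (-1.99, SE 0.375, adjusted p = 0.0101). H2-Aa (chromosome 17, 34282744 to 34287823, minus strand) fell from 196 ± 87.4 to 57.6 ± 33.1 CPM (-1.72, adjusted p = 0.0221). The invariant chain gene Cd74 (chromosome 18, 60803848 to 60812652, plus strand) fell from 698 ± 334 to 248 ± 93.5 CPM (-1.51, adjusted p = 0.0198). Library values of these 3 genes overlapped between the groups, and without sham libraries 303 and 304 H2-Ab1 (-1.23), H2-Aa (-1.26) and Cd74 (-0.88) did not pass, with a list median of -0.70. The list test gave an adjusted p = 8.14e-06, and an adjusted p = 0.199 with an estimated correlation. Markers of the B lineage, which share H2-Aa, H2-Eb1 and Cd74 with this list, fell for 2 of 7 members in the same cells (3 when adjusted over the list alone, median -0.83, adjusted p = 0.0206, and adjusted p = 0.231 with an estimated correlation). Neutrophil markers fell for 1 of 17 (2 when adjusted over the list alone, median -0.44, adjusted p = 0.0264, and adjusted p = 0.491 with an estimated correlation).

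Interferon response genes fell in day 2 monocyte-like cells for 3 of 35 members (17 when adjusted over the list alone, median -0.53), among them Ifi213 (-1.58) and Rtp4 (-1.23). Library values of Rtp4 overlapped between the groups. The adjusted p of the list was 6.46e-08, against an adjusted p = 0.591 with an estimated correlation. The apolipoprotein gene Apoe fell from 774 ± 142 to 329 ± 69.3 CPM (-1.26). The chemokine gene Ccl6 (-0.84), the lysozyme gene Lyz2 (-0.38) and the metalloprotease gene Adam19 (-1.68) fell too, as did the creatine kinase gene Ckb (-1.48), the phosphatase gene Inpp4b (-1.41) and the transcription factor gene Zbtb16 (-1.98). Other rises included Ier3, an early response gene (188 ± 46.2 to 683 ± 234 CPM, 1.83, adjusted p = 0.002). They also included the differentiation inhibitor gene Id1 (1.70), the cytokine signalling suppressor gene Socs3 (1.16) and the lipid receptor gene Trem2 (0.92). Oxidative phosphorylation genes rose for 4 of 46 members (17 when adjusted over the list alone), with the ATP synthase gene Atp5a1 at 0.54 (adjusted p = 1.53e-10, and adjusted p = 0.21 with an estimated correlation). The glycolysis genes Pgk1 (0.56) and Gapdh (0.51) rose, 2 of 15 on that list (2 when adjusted over the list alone, adjusted p = 0.0439, and adjusted p = 0.689 with an estimated correlation). Of the unfolded protein response list 1 of 19 members rose, Sdf2l1 (0.57), and 3 when adjusted over the list alone (adjusted p = 2.53e-05, and adjusted p = 0.135 with an estimated correlation).

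The day 2 count of 239 in monocyte-like cells was 32 without library 305, 115 without sham library 301 (30 cells in this class), 130 without 307 and 142 without sham library 302. It was 108 without both 301 and 302 and 605 without both 303 and 304, with 18 and 22 of the 31 named genes passing and mitosis list medians of 0.91 and 2.00. Of the 31, 11 passed without library 305 and 21 to 29 without any other single library.

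**Figure D2:**
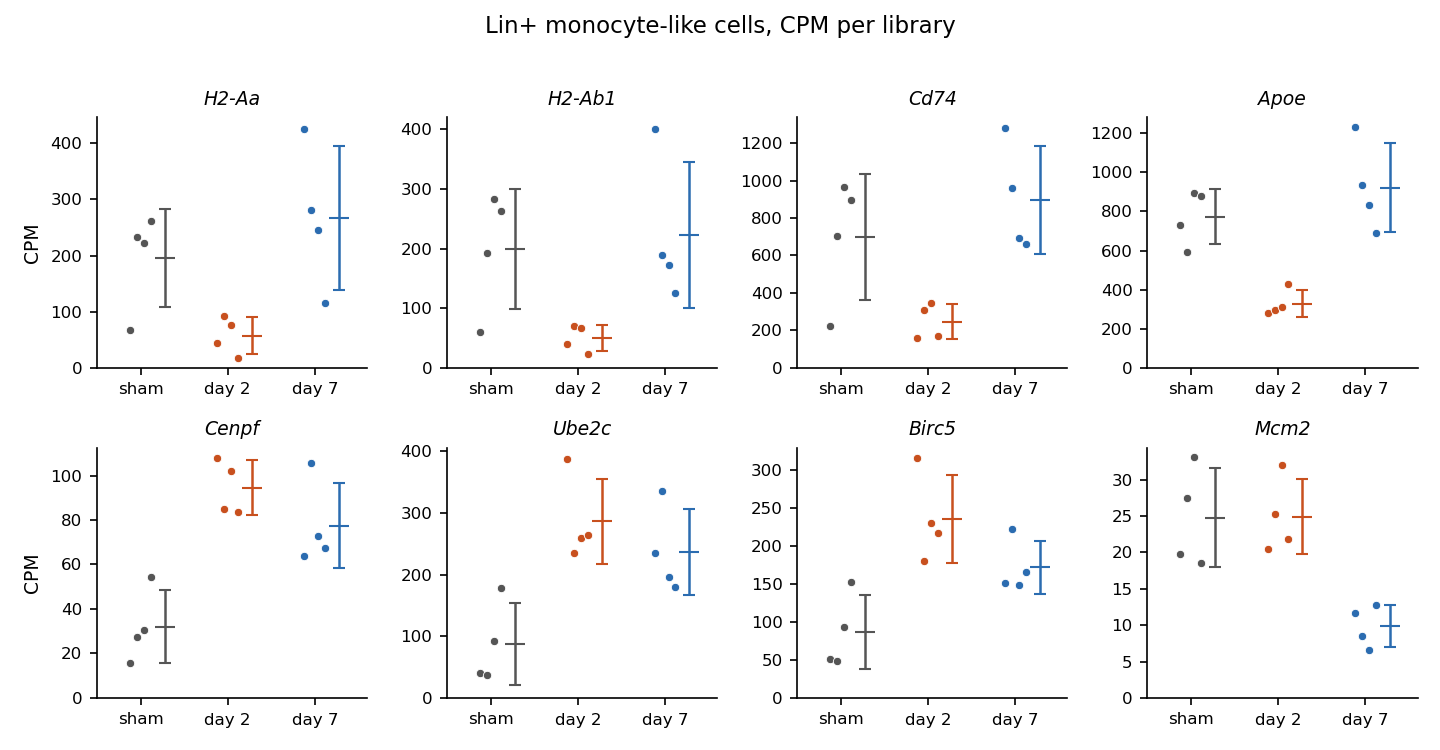
CPM of 8 genes in lineage-positive monocyte-like cells, with 1 point per library in the sham, day 2 and day 7 groups and a bar at the mean with SD beside them. Cd74 lay at 698 ± 334 CPM in sham, 248 ± 93.5 on day 2 and 898 ± 287 on day 7.

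On day 7 no gene passed between monocyte-like cells and sham: edgeR called 0 genes, with 590 at an unadjusted p under 0.05, and DESeq2 called 8 higher and 3 lower. Without both sham libraries 303 and 304 edgeR called 260. The mitosis list had a median of 0.66 with 0 of 33 members rising over all genes and 8 when adjusted over the list alone (adjusted p = 4.98e-28, and adjusted p = 0.171 with an estimated correlation). For the NF-kB and TNF list the median was 0.56, with 4 of 25 members rising when adjusted over the list alone (adjusted p = 1.25e-12, and adjusted p = 0.171 with an estimated correlation). The S phase list had a median of -0.47, with 4 of 28 members falling when adjusted over the list alone (adjusted p = 9.21e-11, and adjusted p = 0.171 with an estimated correlation).

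The direct comparison of the days in monocyte-like cells gave 65 genes higher and 27 lower on day 7. MHC class II rose for 4 of 6 members (6 when adjusted over the list alone, median 1.92). H2-Aa stood at 2.07 (SE 0.372), H2-Ab1 at 2.02 and Cd74 at 1.84, each with an adjusted p = 0.018 and no overlap of library values between the days (n = 4 and 4). The list test gave an adjusted p = 2.02e-11, and an adjusted p = 0.0601 with an estimated correlation. B lineage markers rose for 2 of 7 members (4 when adjusted over the list alone, median 1.03), and this test passed with both settings (adjusted p = 6.02e-05, and adjusted p = 0.0276 with an estimated correlation). MHC class I genes rose for 4 of 14 members (6 when adjusted over the list alone), including H2-Q7 (1.67), a member of a family of similar genes whose value is uncertain (adjusted p = 3.18e-06, and adjusted p = 0.347 with an estimated correlation). Interferon response genes rose for 1 of 35 members (7 when adjusted over the list alone, median 0.41, adjusted p = 4.52e-09, and adjusted p = 0.358 with an estimated correlation). S phase genes fell for 3 of 28 members (18 when adjusted over the list alone, median -0.57), with the replication helicase gene Mcm2 at -1.35 (adjusted p = 2.32e-16, and adjusted p = 0.106 with an estimated correlation). Dmkn (-1.50), Shtn1 (-1.31) and the complement protease gene C1rl (-1.15) were lower on day 7, and Lsmem1 (1.65) was higher. The count of 92 fell to 1 without library 305, 6 without 312, 15 without 309, 19 without 310, 19 without 311, 20 without 307 and 38 without 308, and rose to 162 without sham library 302, 276 without both 301 and 302 and 244 without both 303 and 304. Of the 9 genes named here, 0 passed without library 305, 1 without 309, 3 without 312, 4 without 307, 310 or 311, and 7 without 308.

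Erythroid-like cells of the lineage-positive compartment had 0 genes past the edgeR threshold in each of the 3 contrasts, and 0 by DESeq2. At an unadjusted p under 0.05 edgeR counted 255, 220 and 182 genes for day 2, day 7 and the difference of the days. On day 2 the erythroid markers had a median of 0.52 in this class, with 0 members past the edgeR threshold over all genes or when adjusted over the list alone (adjusted p = 3.14e-06, and adjusted p = 0.308 with an estimated correlation). The primary granule list had a median of -1.11, with 0 of 11 members past the edgeR threshold and 6 falling when adjusted over the list alone (adjusted p = 2.05e-05, and adjusted p = 0.692 with an estimated correlation). The count became 1 on day 2 without library 304 or without 310, and for the difference of the days it became 2 without 309 and 1 without 310. Without both 303 and 304 it was 12 on day 2 and 15 on day 7, and without both 301 and 302 it was 1 for the difference of the days.

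Summed over all lineage-positive cells, where cell makeup and expression within cells both count, day 2 raised 339 and lowered 593 of 11836 genes. The rises included the proteoglycan gene Vcan (2.56, SE 0.487, adjusted p = 0.0211), Ms4a6d (2.09), Trem2 (2.00), Nrg1 (1.89), the cathepsin gene Ctsc (1.34) and the coagulation factor gene F10 (1.04). Wfdc17 (1.76) and Ifitm1 (1.11) rose as in the neutrophil-like class. Thbs1 (-1.33), Sntb1 (-1.16), Cd101 (-1.14), Nfia (-1.08) and the granulocyte growth factor receptor gene Csf3r (-0.74) fell. Library values of Trem2, Ctsc and Csf3r overlapped between the groups. Cell type markers moved with these genes. Monocyte markers had a median of 0.62 (adjusted p = 0.0303), GM precursor markers of 0.51 (adjusted p = 0.00153) and T cell markers of 0.74 (adjusted p = 0.0345). Each of these had an adjusted p = 0.821 with an estimated correlation. Of the GM precursor markers 1 of 13 rose (6 when adjusted over the list alone), and of the monocyte and T cell markers 0 passed either way. Neutrophil markers fell for 1 of 17 (1 when adjusted over the list alone, median -0.17, adjusted p = 0.0459, and adjusted p = 0.876 with an estimated correlation). This count of 932 rested on single libraries, since it was 3 without 307, 3 without sham library 302, 14 without sham library 301, 32 without 305, 572 without 310, 620 without 309 and 1706 without sham library 304. It was 3 without both 301 and 302 and 2891 without both 303 and 304, where the monocyte marker median was 0.16 and 1.35 and that of T cell markers 0.24 and 1.77. Of the 13 genes named here, 1 or 2 passed without library 301, 302, 305 or 307, and 12 or 13 without any other.

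On day 7 the phosphatase gene Dusp2, a brake on MAP kinase signalling, was the 1 gene that passed over all lineage-positive cells (22.5 ± 1.48 to 43.5 ± 4.42 CPM, 0.95, SE 0.085, adjusted p = 0.000281). DESeq2 called 40 genes higher and 8 lower. The edgeR count became 4 without library 303 or 304, 1041 without both and 2 without 311. Day 7 exceeded day 2 for 9 genes and fell below it for 0, among 2142 with an unadjusted p under 0.05, while DESeq2 called 207 higher and 247 lower. The 9 included Thbs1 (1.68), Gabbr1 (0.96), Nt5e (0.94), Gfod1 (0.77) and Susd6 (0.54). This count was 0 without library 302, 307, 308, 309, 310 or 312, 1 without 305 or 311, 5 without 304 and 15 without both 301 and 302.

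GM precursor-like and T cell-like cells made up a larger share of each day 2 library than of any sham library in the lineage-positive compartment, but no share difference passed the permutation test after adjustment. GM precursor-like cells made up 2.74% ± 0.42 of sham cells, 5.48% ± 1.95 on day 2 and 2.51% ± 0.525 on day 7. Day 2 against sham gave an exact permutation p = 0.0286, the smallest that 70 splits allow, and an adjusted p = 0.2. T cell-like cells made up 0.56% ± 0.27, 1.35% ± 0.32 and 1.00% ± 0.73 (exact permutation p = 0.0286 for day 2 against sham, adjusted p = 0.2). With an edgeR test of cell counts, chosen as the alternative, GM precursor-like cells rose on day 2 (0.99, adjusted p = 0.0281) and were lower on day 7 than on day 2 (-1.12, adjusted p = 0.025). Neutrophil-like cells held 83.8% ± 7.29, 72.6% ± 7.62 and 80.4% ± 3.53 (day 2 against sham -11.2 percentage points, exact permutation p = 0.0857, adjusted p = 0.36). At Leiden resolution 1.0, where 2599 cells of this class were in the 3 unnamed clusters, the difference was 6.43 points, and with these joined to the class it was -12.5 points (exact permutation p = 0.0571, adjusted p = 0.257). Monocyte-like cells held 5.23% ± 3.36, 11% ± 6.05 and 7.13% ± 1.91. The sort and the depth gap stated above can both set such shares.

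**Figure D3:**
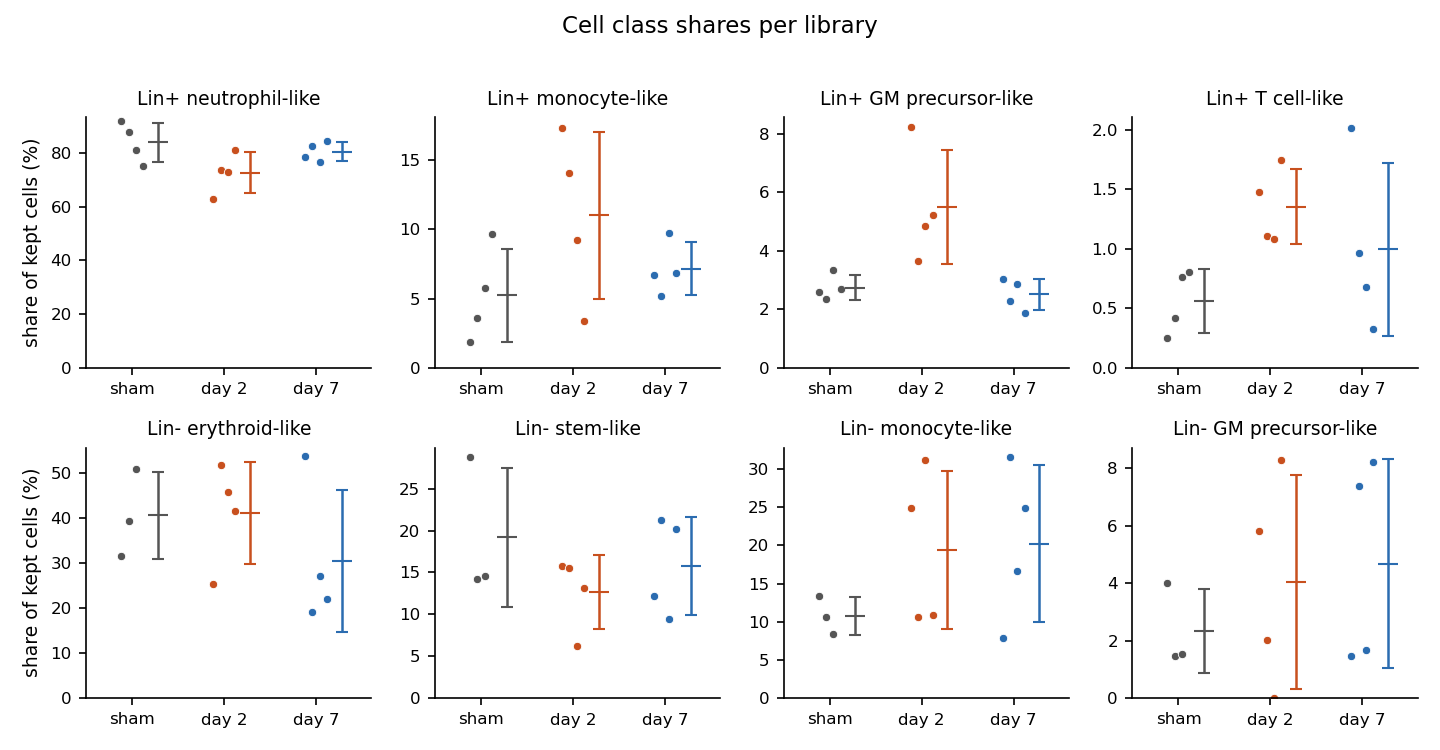
Share of kept cells in percent for 4 classes of lineage-positive (Lin+) and 4 of lineage-negative (Lin-) marrow, with 1 point per library and a bar at the mean with SD. GM precursor-like cells of the lineage-positive compartment lay at 2.74% ± 0.42 in sham and 5.48% ± 1.95 on day 2.

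In the stem-like cells of the lineage-negative compartment, 9 genes rose and 3 fell on day 2, of 5607 tested. Tnfaip3, the A20 inhibitor of NF-kB (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657, minus strand), rose from 122 ± 10.7 to 232 ± 45.2 CPM (0.85, SE 0.169, adjusted p = 0.014, n = 3 and 3). Nfkbia, another NF-kB inhibitor, rose by 0.53. The myeloid transcription factor gene Cebpd (1.62, adjusted p = 0.0259), the granule protease gene Ctsg (0.85) and Plac8 (0.43) rose, together with Dntt (1.00), which encodes the nucleotide-adding enzyme of lymphoid progenitors. Atp8b4 (1.25, adjusted p = 0.00514), the stress kinase gene Mapkapk2 (0.85) and Dusp2 (0.58) were the other rises. Angpt1, a niche factor also made by stem cells, fell from 944 ± 127 to 598 ± 70 CPM (-0.64, adjusted p = 0.0137), and the nuclear RNA Malat1 (-0.29) and the histone gene H3f3b (-0.29) fell slightly.

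The NF-kB and TNF list rose in day 2 stem-like cells with both settings of the list test. Of its members 2 of 16 rose over all genes and 2 when adjusted over the list alone (median 0.34, adjusted p = 1.22e-07, and adjusted p = 0.0127 with an estimated correlation). GM precursor markers in these cells rose for 2 of 10 members, 7 rising and 1 falling when adjusted over the list alone (median 0.54, adjusted p = 6.08e-08, and adjusted p = 0.183 with an estimated correlation). The mitosis list had a median of 0.48 with 0 of 27 members past the edgeR threshold over all genes and 9 rises when adjusted over the list alone (adjusted p = 1.03e-15, and adjusted p = 0.2 with an estimated correlation). Lymphoid progenitor markers rose for 1 of 8 members, Dntt (2 when adjusted over the list alone, median 0.31, adjusted p = 4.66e-06, and adjusted p = 0.186 with an estimated correlation). In stem-like cells of Leiden resolution 1.0, where the lymphoid progenitor-like cluster stands apart, Dntt stood at 0.50 and did not pass. Stem cell self-renewal genes fell for 1 of 11 members, Angpt1 (3 when adjusted over the list alone, median -0.33, adjusted p = 0.00679, and adjusted p = 0.354 with an estimated correlation). Stem markers fell for 1 of 17 (4 when adjusted over the list alone, median -0.25, adjusted p = 0.000701, and adjusted p = 0.254 with an estimated correlation).

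On day 7, 4 genes rose and 3 fell in stem-like cells. Ctsg (0.85), Tnfaip3 (0.81, 122 ± 10.7 to 233 ± 40.9 CPM, SE 0.157, adjusted p = 0.0103, n = 3 and 4) and Plac8 (0.44) were above sham again, and the signalling adaptor gene Tyrobp (0.80) rose. The endothelial and stem cell receptor gene Adgrl4 (-0.46), the transcription factor gene Creb5 (-0.59) and Csgalnact1 (-0.83), an enzyme of chondroitin sulfate synthesis, fell. The NF-kB and TNF list had 1 of 16 members rising, 6 when adjusted over the list alone (median 0.21, adjusted p = 5.74e-05). Myeloid regulators had 0 of 10 members past the edgeR threshold and 3 rising when adjusted over the list alone (median 0.34, adjusted p = 9.74e-05). Both lists passed with an estimated correlation too, each at an adjusted p = 0.0388. Self-renewal genes had 0 of 11 members past the edgeR threshold and a median of -0.40 (6 falls when adjusted over the list alone, adjusted p = 5.74e-05, and adjusted p = 0.355 with an estimated correlation). Stem markers fell for 1 of 17 (6 when adjusted over the list alone, median -0.33, adjusted p = 8.41e-06, and adjusted p = 0.209 with an estimated correlation). GM precursor markers rose for 2 of 10 (8 when adjusted over the list alone, median 0.53, adjusted p = 8.47e-08, and adjusted p = 0.2 with an estimated correlation). Between day 7 and day 2 edgeR called 0 genes, with 196 at an unadjusted p under 0.05 and 0 by DESeq2. The mitosis list had a median of -0.45 in that contrast, with 6 falls when adjusted over the list alone (adjusted p = 1.36e-25, and adjusted p = 0.128 with an estimated correlation).

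These stem-like counts rested on few genes. DESeq2 called 3 higher and 1 lower on day 2, and on day 7 it called 0, with 309 edgeR genes at an unadjusted p under 0.05. The day 2 count of 12 was 3 without sham library 302 and 6 without 308. The day 7 count of 7 was 3 without 302, 4 without 310, 4 without 312, 12 without 304, 14 without 306 and 15 without 303. Of the 12 genes named for day 2, 2 passed without library 302, 6 without 305 or 308, 8 without 303 and 9 without 304, 306 or 310. Of the 7 named for day 7, 1 passed without library 302, 3 without 312 and 4 without 310. At Leiden resolution 1.0, 2 of the 11 tested passed for day 2 and 2 of 7 for day 7, and with all deposited cells 5 of 12 and 2 of 7.

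**Figure D4:**
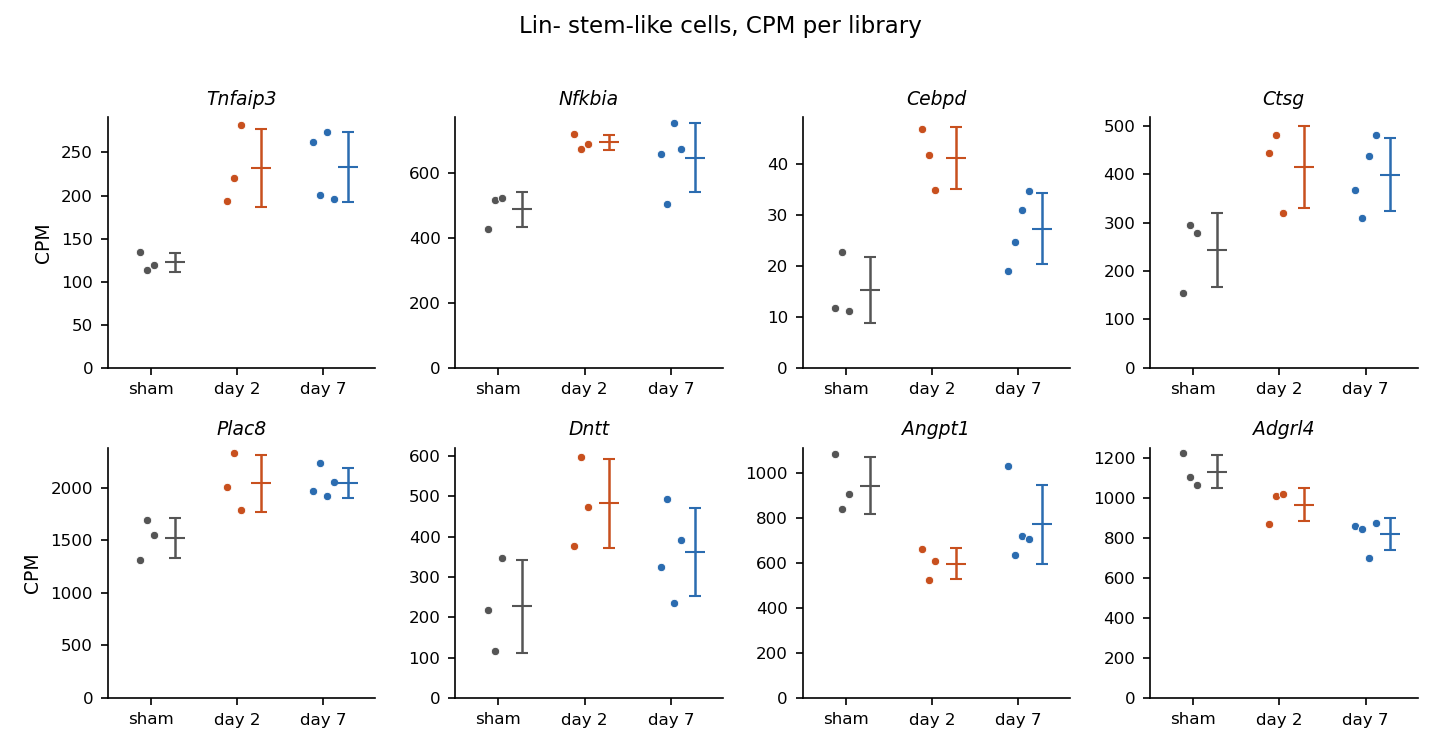
CPM of 8 genes in lineage-negative stem-like cells, with 1 point per library in the sham, day 2 and day 7 groups and a bar at the mean with SD beside them. Tnfaip3 lay at 122 ± 10.7 CPM in sham, 232 ± 45.2 on day 2 and 233 ± 40.9 on day 7.

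In lineage-negative monocyte-like cells 0 genes rose and 10 fell on day 7, of 6861 tested, and the falls included members of the self-renewal and stem marker lists. The transcription factor gene Mecom, needed for stem cell maintenance, fell from 55.9 ± 17.1 to 14.8 ± 3.93 CPM (-1.81, SE 0.261, adjusted p = 0.000615, n = 3 and 4). Prkch (-1.39), Cobll1 (-1.09), Dach1 (-1.06), Gcnt2 (-0.80) and Meis1 (-0.79) fell too, the last with overlapping library values. Self-renewal genes fell for 2 of 9 members (4 when adjusted over the list alone, median -0.79, adjusted p = 1.49e-06, and adjusted p = 0.619 with an estimated correlation). Stem markers fell for 3 of 16 (7 when adjusted over the list alone, median -0.39, adjusted p = 1.15e-06, and adjusted p = 0.422 with an estimated correlation). On day 2 the metallothionein gene Mt1 rose (0.87, adjusted p = 0.00698) and Dach1 fell (-0.99, adjusted p = 0.0276). The immunoglobulin gene Igkc (-4.11, sham libraries from 20.6 to 1053 CPM) fell too, a gene outside the rule that was named after its value was seen. Self-renewal genes had a median of -0.76 on day 2 with 0 of 9 members past the edgeR threshold over all genes. When adjusted over the list alone 4 fell (adjusted p = 9.96e-05, and adjusted p = 0.536 with an estimated correlation). DESeq2 called 1 gene higher and 0 lower on day 2, and 0 higher and 2 lower on day 7. For the difference of the days edgeR called 0 genes, with 114 at an unadjusted p under 0.05 and 0 by DESeq2. The day 7 count of 10 was 0 without library 312, 3 without 302, 4 without 303, 4 without 310, 16 without 309 and 23 without 311. Of the 6 genes named for day 7, 0 passed without library 312, 2 without 302, 3 without 303 or 310 and 4 without 305. The day 2 count of 3 was 0 without library 308, 1 without 305 or 310, 5 without 304 or 312, 7 without 309, 10 without 311 and 12 without 306.

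Summed over all lineage-negative cells, 0 genes passed the edgeR threshold on day 2, on day 7 or between the days, with 466, 552 and 186 at an unadjusted p under 0.05 and 0 by DESeq2 in each. Myeloid regulators had a median of 0.66 on day 2 (adjusted p = 1.55e-05, and adjusted p = 0.648 with an estimated correlation) and of 0.78 on day 7 (adjusted p = 1.7e-08, and adjusted p = 0.432 with an estimated correlation). Markers of GM precursors stood at 0.65 and 0.96 and erythroid markers at -0.19 and -0.41 on the respective days, each with an adjusted p of at least 0.444 with an estimated correlation. In these 3 lists 0 members passed, over all genes or when adjusted over the list alone. Erythroid-like cells also had 0 genes past the edgeR threshold, with 401, 170 and 283 at an unadjusted p under 0.05 and 0 by DESeq2, and 1 on day 2 without library 308. Their interferon response list gave an adjusted p = 0.00942 for a lower level on day 2, and an adjusted p = 0.689 with an estimated correlation.

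Class shares of lineage-negative cells varied widely between libraries. Erythroid-like cells held 40.6% ± 9.70 in sham, 41.1% ± 11.3 on day 2 and 30.5% ± 15.8 on day 7. Stem-like cells held 19.2% ± 8.31, 12.7% ± 4.45 and 15.8% ± 5.84, and monocyte-like cells 10.8% ± 2.47, 19.4% ± 10.3 and 20.2% ± 10.3. GM precursor-like cells held 2.33% ± 1.45, 4.04% ± 3.73 and 4.68% ± 3.63. With 3 sham libraries the exact permutation p used here, the smaller tail doubled, cannot go below 0.0571 for a contrast with sham, and the lowest adjusted p over all classes and contrasts was 0.8.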

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

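The fits without a pair of sham libraries and the tests of neutrophil clusters, depth, gene length, RNA from B cells and free RNA from myeloid cells were chosen after the gene counts had been seen. Those of drawn UMI counts, RNA from B cells and free RNA were chosen after the values they bear on, and only the comparisons with other splits of the libraries were planned.

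In groups of 4 libraries, 22 of 308 sets of values had 1 library far from the other 3. Chance flags about 1 in 20 groups. Among lineage-negative day 7 libraries, library 312 had 4402 kept cells against 297 to 422 in the others, and 3.486e+07 gene counts against 2.476e+06 to 3.181e+06. In library 311 37.7% of kept cells were in the unnamed cluster 5 led by Apoe and Clec4d, against 11.4% to 15.4% in the others. Its Adgrl4 level in stem-like cells was 698.6 CPM against 846.2 to 873.3. In the lineage-positive compartment, B cell-like cells made up 1.75% of library 312 against 3.68% to 3.95%. Unnamed cluster 13, led by Pparg and Adgre4, made up 0.329% of library 305 against 0.679% to 0.699%. In neutrophil-like cells, Clec4e was 512.8 CPM in library 306, Ldha 238.6 and Maml3 43.4 in sham library 302, Klf4 9.87 in sham library 301 and Ifi204 13.04 in library 305. In monocyte-like cells, Ier3 was 1031 CPM in library 306, Cdca3 61.6 in sham library 304, Socs3 41.4 in sham library 303 and Zbtb16 44.7 in sham library 302. Library 305 stood apart in that class for Atp5a1 (404.2 CPM), Gapdh (1339 CPM) and H2-Q7 (7.15 CPM). Over all lineage-positive cells, Trem2 was 7.48 CPM in sham library 304, Ctsc 25.01 in sham library 301, Wfdc17 183.2 in library 307 and Gabbr1 9.51 in library 305.

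The effects of day 7 and day 2 differed by a direct test of the contrast for 9 genes over all lineage-positive cells, 86 in neutrophil-like and 92 in monocyte-like cells. With the preset correlation, the same contrast passed for 14 gene lists over all lineage-positive cells, 11 in neutrophil-like, 14 in monocyte-like and 5 in erythroid-like cells. In lineage-negative cells it passed for 6 lists over all cells, 5 in erythroid-like, 1 in monocyte-like and 1 in stem-like cells, and with an estimated correlation 0 of these passed. In neutrophil-like cells the differences were Thbs1 1.55, Gabbr1 0.75, Btbd19 0.68, H2-K1 0.54 and Smad3 0.53. Falls were Rpl12 -0.69, Hist1h2ab -0.71, Stfa2 -1.07, Cstdc5 -1.07 and Wfdc17 -1.09. In monocyte-like cells differences were H2-Aa 2.07, H2-Ab1 2.02, Cd74 1.84, H2-Q7 1.67, Lsmem1 1.65, Mcm2 -1.35, Dmkn -1.50, Shtn1 -1.31 and C1rl -1.15. Over all cells they were Thbs1 1.68, Gabbr1 0.96, Nt5e 0.94, Gfod1 0.77 and Susd6 0.54. Of 37 genes looked at in both compartments, 0 moved in opposite directions with no overlap of library values in either compartment. Opposite changes with any overlap were not counted, so this says little about agreement in direction. In the cell tag counts, which no comparison used, the own tag of library 305 took a median of 52.0% of tag counts per kept cell, above the highest sham library at 50.4%.

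The day 2 changes in lineage-positive neutrophil-like cells had a median size of 0.44 over the 706 genes, each taken in its direction in the class. Fitted alone, cluster 1 gave 0.35 (95% bootstrap interval over genes 0.33 to 0.37) and cluster 2 gave 0.44 (0.41 to 0.46). This argues against a shift between them as the whole cause. Less the median of genes of like exon length it was 0.38 (0.36 to 0.40). Among cells of 3000 to 8000 UMIs the median size was 0.27 (0.25 to 0.29) over 666 of the genes. There day 2 cells (library medians 4943 to 5211 UMIs) still exceeded sham cells (4451 to 4729). With UMI counts drawn alike the median size was 0.19 (0.17 to 0.22), but the cluster makeup differed. With UMI counts drawn alike within clusters 0, 1 and 2 it was 0.28 (0.25 to 0.30), 552 of 608 genes keeping their direction. Drawn at random it was 0.43, so part of the size went with UMI counts. The genes were called in these cells, so depth, gene length and makeup within clusters stay open. A response of the cells to ischemia stays open as a hypothesis, as does a difference in handling. Sham libraries fell into 2 pairs, also in cell makeup, and no label gives a batch.

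The day 2 fall of MHC class II in monocyte-like cells had a median of -1.61, and the class could have lost RNA from B cells, which carry these genes. The summed CPM of B lineage markers outside MHC class II had a log2 ratio of -0.18 (bootstrap interval over libraries -0.39 to 0.01). Which markers carry this sum was not tested, so that source stays open. Among monocytes of 5000 to 15000 UMIs the median fall was 1.41, with a bootstrap interval over the 6 genes, not over libraries, of 0.09 to 1.84. Library medians of UMIs still did not overlap there (8464 to 10151 on day 2, 6459.5 to 8031 in sham). Depth therefore stays open. The median fall was 1.91 without sham libraries 301 and 302 and 0.70 without 303 and 304, so its size rested on which sham libraries were used. A shift among monocyte subtypes, RNA from unnamed cluster 10 (Cd209a, H2-Ab1), a difference in handling and a change within cells were not tested and stay open.

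In lineage-negative stem-like cells 10 genes were called higher, 9 on day 2 and 4 on day 7, and free RNA from myeloid cells is a candidate explanation because Ctsg and Tyrobp are abundant there. The 10 genes would need a median of 57.2% of monocyte-like RNA (bootstrap interval over genes 16.9% to 100%) or 63.0% of GM precursor-like RNA (15.9% to 100%), with 100% where no share reaches the level, as for Dntt, Dusp2, Nfkbia and Tnfaip3. The abundant markers Mpo, Elane, Prtn3, Ms4a3, Clec12a and Cst7 allow a median of 4.20% (3.33% to 13.5%) and 1.33% (0.66% to 4.38%). The called genes Ctsg and Plac8 were left out of these markers, which can lower the share allowed. The comparison therefore cannot decide for genes whose level a share can reach. For Dntt, Dusp2, Nfkbia and Tnfaip3, which no share reaches, the values argue against free RNA from these 2 classes. The rise of Ctsg would need 2.48% (day 2) and 1.82% (day 7) of GM precursor-like RNA. That of Tyrobp on day 7 would need 12.7% of monocyte-like RNA, so for both genes free RNA stays open. A higher share of myeloid-primed or lymphoid progenitors within the class, or a change within cells after ischemia, stays open as a hypothesis.

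Other ways to split the same libraries were counted for each gene count, with the real split among them. Only the real split, 1 of 35, gave as many genes for the day 2 counts of all lineage-positive cells (932, highest other split 311), neutrophil-like cells (706, highest other 183) and monocyte-like cells (239, highest other 15). The same holds for day 7 in neutrophil-like cells (49, highest other 0), for the difference of the days over all cells (9, highest other 0), in neutrophil-like (86, highest other 0) and in monocyte-like cells (92, highest other 1). It also holds for day 7 in stem-like cells (7, highest other 5), but there DESeq2 called 0 genes and the edgeR count was 3 without library 302 and 4 without 310 or 312. A share of 1 of 35 is the lowest possible, and many such counts on shared libraries were compared. Lineage-positive sham libraries also fell into pairs, so these splits do not exclude chance. Leaving out 1 library, the lowest of the other counts were 3 (all cells), 236 (neutrophil-like) and 32 (monocyte-like) on day 2, 2 on day 7 in neutrophil-like cells, and 0 (all cells), 36 (neutrophil-like) and 1 (monocyte-like) for the difference of the days. For day 7 over all lineage-positive cells another split gave as many (1, highest other 2, 2 of 35 splits), so that count does not stand apart from chance. Nor do the counts of lineage-negative monocyte-like cells on day 2 (3, highest other 13, 7 of 35 splits) and day 7 (10, highest other 33, 3 of 35 splits). For stem-like cells on day 2 there are 10 splits, too few for a share under 0.05 (12, highest other 2). Where the real count was 0, all 35 splits gave as many. The highest other counts there were 29, 6 and 1 for day 2, day 7 and their difference in lineage-positive erythroid-like cells, and 2 for day 7 in monocyte-like cells. In lineage-negative cells they were 1, 346 and 1433 over all cells, 3, 0 and 46 in erythroid-like cells, 33 for the difference of the days in monocyte-like cells and 4 in stem-like cells. The 1433 genes came from libraries 305, 310, 311 and 312 (19.2% to 27.0% erythroid-like) against the remaining 4 (41.5% to 53.8%), a split along cell makeup.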

How the results depend on the processing

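Alternatives by Scrublet score, neutrophil cluster or drawn cells, joined clusters or a left-out sham pair were chosen after the results were seen. The planned removal of cells called by Scrublet was not run, since its threshold marked 0 cells. Over all alternatives, 370 values of main results stayed on their side and 166 moved, and of single genes and shares 3152 stayed the same, 854 lost the threshold, 2 gained it and 39 changed sign. RLE scaling moved no count by more than 1.5 times. Without a low-count filter more genes were tested. The counts for day 2, day 7 and their difference then became, where they moved, 39 and 80 (day 7 and difference) over all lineage-positive cells, 1207, 588 and 366 in neutrophil-like, 490, 133 and 355 in monocyte-like and 12, 11 and 24 in erythroid-like cells. In lineage-negative cells they became 1 and 2 (day 2, day 7) in erythroid-like, 27, 33 and 2 in monocyte-like and 13 (day 7) in stem-like cells. DESeq2 gave 1468, 48 and 454 over all lineage-positive cells, 190 and 174 in neutrophil-like cells (day 7, difference) and 11 in monocyte-like cells (day 7). In lineage-negative cells it gave 1 and 2 in monocyte-like and 4 and 0 in stem-like cells (day 2, day 7). With all deposited cells the counts were 3 for day 7 over all lineage-positive cells, 3 for the difference in lineage-negative erythroid-like cells, 0 and 2 in lineage-negative monocyte-like and 5 and 2 in stem-like cells (day 2, day 7). Leiden resolution 1.0 gave 386, 111 and 51 in neutrophil-like cells, where 3 clusters of the class stayed unnamed, and with these joined the counts moved by less than 1.5 times. It gave 14 and 1 in lineage-negative monocyte-like cells (day 2, difference) and 4 and 3 in stem-like cells (day 2, day 7). Cluster 1 alone gave 220, 19 and 3 and cluster 2 alone 264 (day 2) and 9 (difference), with fewer cells summed. Neutrophil-like cells drawn to like UMI counts gave 121 and 13 (day 7, difference), those drawn alike within clusters 234, 20 and 7, and those drawn at random 238, 13 and 6. Removing the highest Scrublet scores gave 2, and setting clusters aside 3, for day 7 over all lineage-positive cells. Leaving out lineage-negative libraries with under 200 cells gave 18 in monocyte-like (day 2) and 14 in stem-like cells (day 7). With the replicate number as a block, the counts became 502, 2 and 1 over all lineage-positive cells, 53 for the difference in monocyte-like and 1 for it in erythroid-like cells, and the block moved no other count by more than 1.5 times. Deviations of libraries with the same number correlated between -0.339 and 0.169, so the numbers do not pair the libraries. In lineage-negative cells no paired fit was planned, because the labels number these libraries without tying a number to a tag. An estimated correlation left 3 of 206 passing gene list tests. Without sham libraries 301 and 302 the counts became 3 (day 2) and 15 (difference) over all lineage-positive cells, 411 and 331 in neutrophil-like, 108 and 276 in monocyte-like and 1 (difference) in erythroid-like cells. Without 303 and 304 they became 2891 and 1041 (day 2, day 7) over all, 2169, 1413 and 192 in neutrophil-like, 605, 260 and 244 in monocyte-like and 12 and 15 (day 2, day 7) in erythroid-like cells. The edgeR test of cell counts passed for 1 class, lineage-positive GM precursor-like cells, in 2 contrasts. The sign of the neutrophil-like share turned at resolution 1.0 (6.43 points on day 2, 8.13 on day 7) because 2599 of its cells stayed unnamed there, and with these joined it was -12.5 and -3.41 points. Other signs turned for the lineage-positive erythroid-like share on day 7 with all cells (-0.528). They turned for the lineage-negative erythroid-like share on day 2 with all cells (-0.679) and with clusters set aside (-0.054), the lineage-negative monocyte-like share between the days with all cells (-0.622) and the GM precursor-like share between the days at resolution 1.0 (-0.137, where that class held 847 cells against 554). Cd101 (0.15) turned at resolution 1.0 without the unnamed clusters and Rpl12 (0.12) in cluster 2. In cells of like UMI counts 8 named genes turned on day 2, Cd101 (0.61), Maml3 (0.42), Ifi204 (0.18), Grk5 (0.16), Cyba (-0.015), Anxa1 (-0.093), Lcn2 (-0.21) and Serpinb1a (-0.25), and within clusters Cd101 (0.047), Serpinb1a (-0.044) and Lcn2 (-0.10). Leaving out 1 library gave 3 to 1706 genes on day 2, 1 to 4 on day 7 and 0 to 11 between the days over all lineage-positive cells. It gave 236 to 1329, 2 to 279 and 36 to 141 in neutrophil-like cells, 32 to 291 (day 2) and 1 to 162 (difference) in monocyte-like cells, and 0 to 1 (day 2) and 0 to 2 (difference) in erythroid-like cells. In lineage-negative cells it gave 0 to 1 in erythroid-like cells (day 2), 0 to 12, 0 to 23 and 0 to 2 in monocyte-like cells, and 3 to 12 and 3 to 15 in stem-like cells (day 2, day 7). Share differences ranged over both signs, in points, from -0.147 to 1.14 for lineage-positive erythroid-like cells (day 7), -0.14 to 1.01 (day 2) and -0.09 to 0.742 (difference) for B cell-like cells. They ranged from -4.03 to 5.72 for lineage-negative erythroid-like (day 2), -5.96 to 1.34 for stem-like (day 7), -2.97 to 4.98 for lineage-negative monocyte-like (difference), -1.09 to 0.261 for megakaryocyte-like (day 2) and -0.696 to 2.07 for lineage-negative GM precursor-like cells (difference). Apart from the fewer libraries, cells, clusters or tested genes named, the cause was not tested. In simulated counts at a 2-fold change, recovery was 28.4% in lineage-positive erythroid-like cells and 52.2% in lineage-positive monocyte-like cells, against 67.2% to 83.6% in the other fits.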

Other observations

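The lineage-negative cluster without a name, led by Apoe, Clec4d and F2r, the lineage-negative megakaryocyte-like class and the lineage-positive GM precursor-like and B cell-like classes were not among the planned fits. They were fitted in addition with edgeR in the same way, and these tests were chosen after the results above were seen. Libraries with under 20 cells stayed out: 307 for the unnamed cluster, sham library 301 for B cell-like cells, and 306, 307, 310 and 311 for megakaryocyte-like cells. In megakaryocyte-like cells edgeR called 0 genes in each of the 3 contrasts, with 259, 160 and 139 at an unadjusted p under 0.05 for day 2, day 7 and the difference of the days, and 0 by DESeq2. In that unnamed cluster, 11 of 5820 genes rose on day 7 against sham and 0 fell, with 17 higher and 2 lower by DESeq2. The immediate early gene Fos rose from 2262 to 4064 CPM (0.85, adjusted p = 1.41e-07) and the RNA-destabilizing factor gene Zfp36 from 234 to 507 CPM (1.10, adjusted p = 3.12e-06). Fosb (0.47), Btg2 (0.60), Klf2 (0.50), Klf4 (0.87), Dusp2 (0.82) and Mir142hg (0.64) rose as well, together with the adhesion receptor gene Adgre5 (1.17), Rgcc (0.82) and the tubulin gene Tuba1a (0.93). On day 2 Fos (0.74), Zfp36 (0.89) and Klf2 (0.56) rose there and 0 genes fell, with the same numbers by DESeq2, and between the days 0 genes passed, with 216 at an unadjusted p under 0.05 and 0 by DESeq2.

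In lineage-positive GM precursor-like cells the granule gene Olfm4 fell on day 2 from 87.6 to 23.3 CPM (-1.92, adjusted p = 0.00118), the 1 gene that passed, and DESeq2 called 0 higher and 1 lower. Dusp1, a phosphatase that ends MAP kinase signals, rose on day 7 from 532 to 926 CPM (0.80, adjusted p = 0.00275). G0s2, an inhibitor of fat breakdown, rose from 127.5 to 283.9 CPM (1.15, adjusted p = 0.00631), and Aff3 fell from 56.1 to 15.8 CPM (-1.81, adjusted p = 0.0146), with 8 genes higher and 2 lower by DESeq2. Between the days Thbs1 was higher on day 7 (1.75, adjusted p = 0.00896), the 1 gene that passed, and DESeq2 called 1 gene higher. All genes named in this part were chosen after their values were seen. In B cell-like cells edgeR called 0 genes against sham, with 152 on day 2 and 190 on day 7 at an unadjusted p under 0.05 and 0 by DESeq2. The difference of day 7 and day 2 passed for the cytokine gene Il1b (3.17) and for Thbs1 (4.16), each with an adjusted p = 0.0208. Both genes lead neutrophil clusters of the same compartment, and whether their counts came from B cells was not tested. The tag of a library was the highest of the 12 tags in 89.2% to 100% of its lineage-positive cells. It took a median of 26.6% (day 7 library 310) to 51.8% (day 2 library 305) of the tag counts per cell over all deposited cells, so the assignment of cells to libraries was not rechecked in full.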
